A study of Mus musculus with 24 samples.

How the data were processed

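MicroRNA abundance was measured by real-time PCR in the soleus of 12 male mice, each aged 12 weeks. The mice formed 4 groups of 3: MCK-PPARa transgenic mice, their non-transgenic littermates (NTGa), MCK-PPARb transgenic mice and their non-transgenic littermates (NTGb). Per the labels' protocols, total RNA was extracted with RNAzol B and run as TaqMan assays with a FAM label for 40 cycles. Each RNA was run on 2 cards of 384 wells, called A and B, so the 24 deposited samples were 12 animals. The labels call the replicates biological, and they were treated here as separate animals.

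Per the file headers and the values themselves, the authors deposited 1 cycle threshold (Ct) per well, not normalized, with an empty cell where no Ct was called. A Ct is the cycle at which fluorescence crosses a threshold, so a lower Ct means more template. The analysis software, the threshold and the baseline settings are not given in the sources used here. Card A held 375 microRNA assays and card B 209, together 584, of which 517 carried mouse and 67 rat names. The rest of the wells held endogenous small RNA controls and a plant microRNA, ath-miR159a, for which no well on either card had a Ct. Every data column was matched to a sample by its name, and 0 columns were left unmatched.

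Wells of the same assay on a card were averaged, with an empty well beside a called one counted as Ct 40; this rule was chosen after the files were seen. A microRNA counted as detected in an animal at a Ct under 35. The relative abundance on the log2 scale was the mean Ct of the microRNAs detected in all 12 animals on that card (149 on card A, 59 on card B) minus the Ct of the microRNA. A fold change read from it assumes that template doubles in each cycle. After scaling, values not detected were set to 1 floor per card, which was -6.56 on card A and -5.66 on card B, and so was any value under it. A microRNA was tested if it was detected in all 3 animals of at least 1 group, which left 268 assays, 180 from card A and 88 from card B. A microRNA at the floor in all 3 animals of a group has only a bound there, given as "at least N-fold". Such a group also adds an SD of 0 to the shared spread, so the p-values of that microRNA may be too small.

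Group means were fitted over all 12 animals with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 4 groups shared an estimate of the spread with 8 residual degrees of freedom. The comparisons were MCK-PPARa against NTGa, MCK-PPARb against NTGb, the difference of these effects, and NTGa against NTGb. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 268 assays, and a microRNA was called changed at an adjusted p under 0.05. The 20 lists of microRNAs described in the report were fixed before the data were examined, as were the alternatives except those named as added later. Lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, adjusted over 13 lists, and again with an estimated correlation and with fry. Single values such as the number of detected microRNAs were compared with an exact permutation test, for which 3 animals against 3 cannot give a p under 0.1.

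The microRNAs named in the text follow a fixed rule. All tested members of the myosin-gene and muscle-enriched lists were eligible, followed by the 10 called microRNAs with the largest rise and the 10 with the largest fall. Where fewer than 10 passed in a direction, those of lowest unadjusted p were added and are given as values that did not pass. For the difference of effects the 10 of lowest p were eligible, and for each list up to 4 members of lowest p. The microRNAs called between the control groups, and miR-208 and miR-122, were named outside this rule after their values were seen.

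Precision was limited by Ct. The 150 assays of card B with a pair of wells differed between those wells by a median of 0.0529 Ct below Ct 25, 0.192 between 25 and 30, 0.381 between 30 and 32 and 0.755 between 32 and 35, where 38.5% of well pairs differed by more than 1 Ct. The median residual SD between animals of a group was 0.26 on the log2 scale for microRNAs below Ct 25 and 0.74 for those between 32 and 35. The fit was tested on simulated data made from the real means and residual SDs for MCK-PPARa against NTGa with 268 assays and 30 changed microRNAs in each of 20 sets. It recovered 42.5% of 2-fold, 81.0% of 4-fold and 91.0% of 8-fold changes, and 4.67% of its calls were false. All assays were simulated as independent, so the share of false calls may not hold for microRNAs that vary together within an animal. The changed microRNAs were drawn only from assays above the floor in every animal. The recovered shares therefore do not apply to microRNAs at the floor in some animals, such as miR-215, miR-331-5p and miR-208b. In the same sets, a list of 19 microRNAs shifted by 0.5 in MCK-PPARb against NTGb passed camera at p under 0.05 in 100% of sets, and an unshifted list in 5% of them. Members were simulated as independent, so these shares do not apply to lists of correlated members, such as the Dlk1-Dio3 cluster with an estimated correlation of 0.307.

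The alternatives changed the reference for scaling, the detection limit, the treatment of undetected values, the filter, the animals in the fit, the adjustment, the variance model and the list test, and left out each animal in turn. The mean over called wells only, and comparisons with the other line's controls or with all 6 controls, were added after the data were seen. Gene names next to or overlapping a microRNA gene came from a RefSeq table of assembly GRCm38.p6. The deposited files name no genome build, so no coordinates are given.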

Results

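The study asked how microRNAs of skeletal muscle differ when a peroxisome proliferator-activated receptor is raised there. PPARα and PPARβ are nuclear receptors that switch on genes of fatty acid use. In MCK-PPARa and MCK-PPARb mice, the receptor is expressed from a transgene active in muscle. The soleus, a postural muscle of the calf rich in slow-twitch fibres, was taken from 3 transgenic mice and 3 non-transgenic littermates of each line, called NTGa and NTGb. Of 584 microRNA assays, 248 to 296 were detected per animal. The mean was 278 ± 1.73 (SD, n = 3) in MCK-PPARa against 273 ± 6.03 in NTGa (exact permutation test, p = 0.3), and 277 ± 6.56 in MCK-PPARb against 268 ± 24.8 in NTGb (exact p = 0.6). The mean Ct of the endogenous small RNA controls differed by 0.0114 cycles between MCK-PPARa and NTGa (exact p = 1, n = 3) and by -0.11 cycles between MCK-PPARb and NTGb (exact p = 0.7, n = 3). An exact test of 3 animals against 3 cannot go below p = 0.1.

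In MCK-PPARa soleus, miR-499 fell 12.6-fold against NTGa. miR-499 is made from an intron of Myh7b, a slow-type myosin gene, and acts to maintain slow fibres. Its Ct was 28.0 ± 0.0741 (SD, n = 3) in NTGa and 31.9 ± 0.482 in MCK-PPARa, a log2 change of -3.66 (SE 0.30, limma adjusted p = 3.94e-05), with 3 of 3 transgenic animals below every control. miR-190b fell 4.76-fold (log2 -2.25, SE 0.30, adjusted p = 0.00148). A rat assay of the same name measured log2 -2.21 (SE 0.58, adjusted p = 0.087), which did not pass. The 3 microRNAs called higher, miR-215, miR-194 and miR-192, are abundant in liver, gut and kidney epithelium. miR-215 had no Ct in any NTGa animal and a Ct of 32.4 ± 0.464 in MCK-PPARa, a rise of at least 4.46-fold (limma adjusted p = 3.29e-04). Its log2 SD was 0.48 in MCK-PPARa but 0 in NTGa and MCK-PPARb, both at the floor, so this p may be too small. miR-194 rose 2.64-fold (log2 1.40, SE 0.23, adjusted p = 0.00688) and miR-192 rose 2.02-fold (log2 1.01, SE 0.22, adjusted p = 0.0425). The RefSeq table places Mir215 beside Mir194-1 and Mir192 beside Mir194-2.

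**Figure D1:**
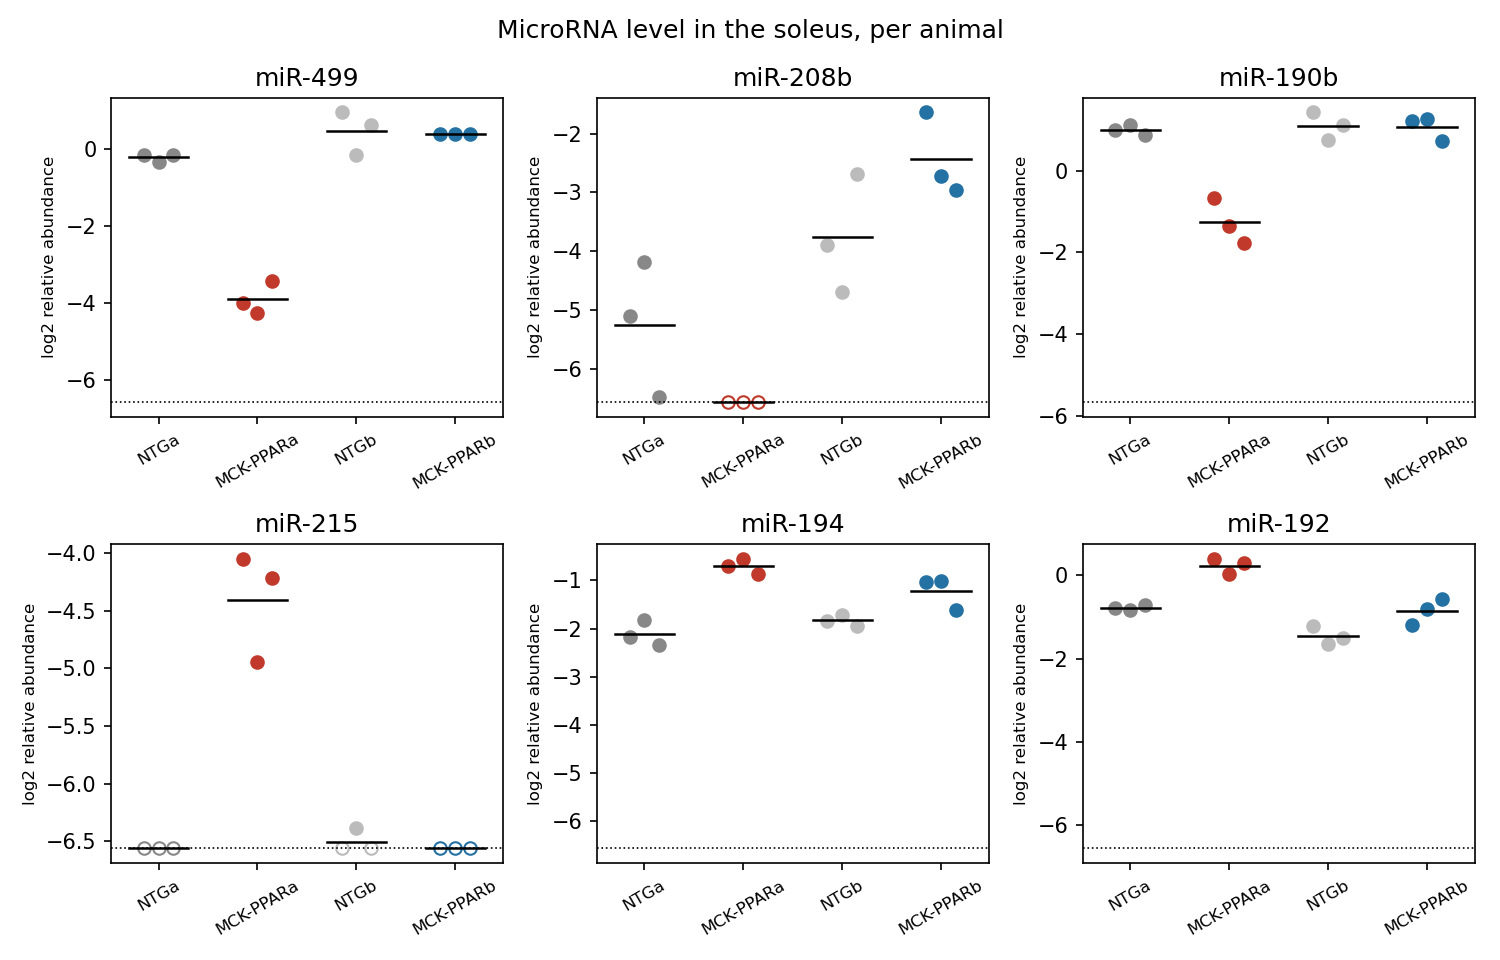
Log2 relative abundance (vertical axis) of 6 microRNAs in each of the 12 animals, by group. Bars are means of 3 animals, open circles are values at the floor and the dotted line is the floor; miR-499 lies at -0.23 in NTGa and -3.89 in MCK-PPARa, and miR-215 is at the floor in all 3 NTGa animals.

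miR-331-5p was also called lower in MCK-PPARa, at least 2.63-fold (adjusted p = 0.0425). It was at the floor in all 3 MCK-PPARa animals and also in all 3 NTGb controls, so NTGa held the higher level. The SD of 0 in these groups may make its p too small. Together with the microRNAs above, 6 of 268 tested microRNAs were called, 3 higher and 3 lower. At an unadjusted p under 0.05 there were 44 (20 higher, 24 lower). The groups did not overlap for 69 microRNAs, or 25.7%, where chance gives 10% on average. MicroRNAs are not independent, and this share was not compared with that of other splits of the animals. With U6 snRNA as reference or with no scaling, 1 rose and 3 fell; with the endogenous controls, 2 rose and 2 fell. The call of miR-192 was lost without any 1 of the 6 animals (adjusted p 0.055 to 0.204) and that of miR-331-5p without any 1 of them except NTGa replicate 1 (up to 0.142). miR-192, miR-194 and miR-331-5p also lost their calls under 6, 2 and 9 of the other alternatives, whose adjusted p reached 0.177, 0.0967 and 1.

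Other muscle-enriched microRNAs in MCK-PPARa did not pass. miR-208b, encoded in the slow myosin gene Myh7, had a Ct of 31.8 to 34.4 in NTGa, while in MCK-PPARa 2 of 3 animals had no Ct and the other had 39.2, at least 2.48-fold lower (adjusted p = 0.334). Over the alternatives the adjusted p of miR-208b ran from 6.72e-04 to 1, and it was called with no detection limit (log2 -6.26) and against NTGb (-2.80, adjusted p = 0.0356). The -6.26 rests on 2 animals without a Ct and 1 at 39.2, and the -2.80 on 3 animals at the floor. Neither value therefore measures the size of the fall. Against NTGa, the value of miR-208b was -0.77 without NTGa replicate 2. The general muscle microRNAs miR-1, miR-133a and miR-133b had log2 changes of -0.11 (95% interval -0.61 to 0.38), -0.08 and 0.13; the sign of each turned under at least 1 other reference for scaling. miR-206, which is typical of the soleus, was at 0.36 (adjusted p = 0.517) and miR-486 at 0.68 (SE 0.23, limma adjusted p = 0.206). Of the 7 tested members of the muscle-enriched list, 1 fell, and the list as a whole did not shift (camera adjusted p = 0.436). Adjusted over the list alone, 1 of 7 muscle-enriched and 1 of 2 tested myosin-gene microRNAs passed, miR-499 in both. The untested myosin-gene member, miR-208, had no Ct in NTGa or MCK-PPARa.

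**Figure D2:**
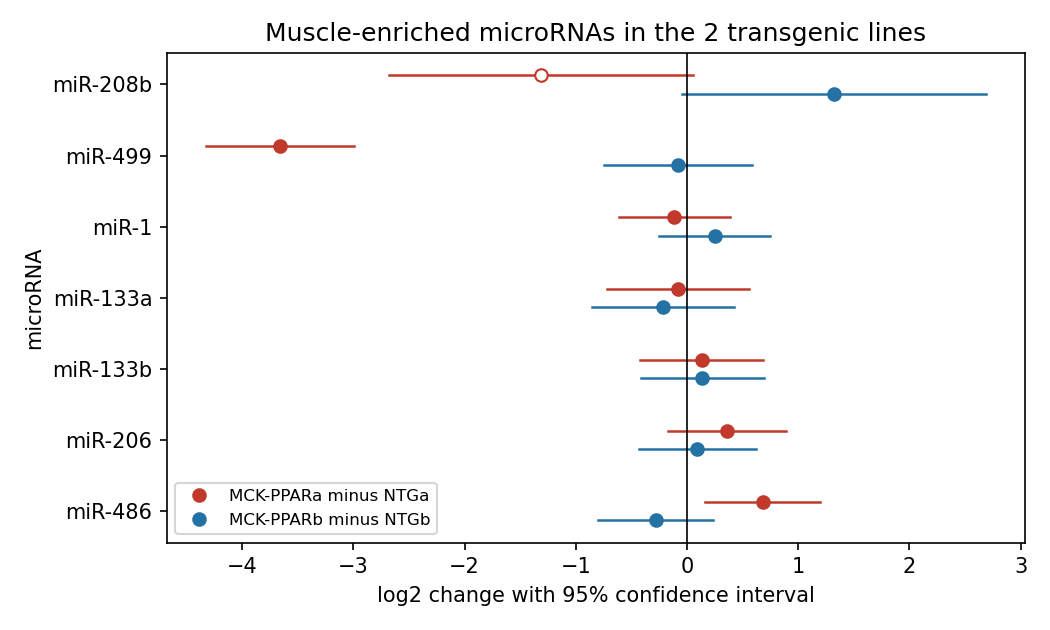
Log2 change (horizontal axis, with 95% confidence interval) of the 7 tested muscle-enriched microRNAs, MCK-PPARa minus NTGa in red and MCK-PPARb minus NTGb in blue. miR-499 lies at -3.66 in MCK-PPARa and -0.08 in MCK-PPARb, where its sign depends on the reference for scaling; the open circle of miR-208b is a bound, since it was at the floor in all 3 MCK-PPARa animals.

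The remaining microRNAs of lowest p in MCK-PPARa are values that did not pass. On the higher side were miR-425 (log2 3.19, adjusted p = 0.0645), miR-185 (1.34), miR-339-5p (2.23), miR-9 (1.62), miR-34a (1.04) and miR-221 (2.22). On the lower side were miR-509-3p (-2.26, adjusted p = 0.0522), miR-434-3p (-1.43), miR-20b (-1.90), miR-181c (-1.07), miR-741 (-2.02) and miR-136 (-1.20, or -0.78 without NTGa replicate 3). The levels of miR-425, miR-509-3p and miR-741 took the opposite sign when MCK-PPARa was set against NTGb. miR-434-3p stood at -0.92 in MCK-PPARa, 0.50 in NTGa and -0.60 in NTGb, and miR-136 at -1.97, -0.78 and -1.57. Their changes were thus smaller against NTGb, as were those of miR-339-5p, miR-9, miR-221 and miR-20b. Those of miR-185, miR-34a and miR-181c were not. Some animals were at the floor for miR-9, miR-221 and miR-425 in NTGa and for miR-741 and miR-181c in MCK-PPARa, which limits these sizes.

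No list passed camera in MCK-PPARa, with adjusted p from 0.436 to 0.931 over 13 lists. Of 11 metabolism-associated microRNAs, 9 had positive values, led by miR-33* at 1.37 (limma adjusted p = 0.226). Of 5 miR-30 family members, 5 had negative values (mean -0.27), and of 9 let-7 members 7 were positive (mean 0.18). The Dlk1-Dio3 cluster, a large imprinted group of microRNA genes, had 11 of 19 members negative (mean -0.23, camera adjusted p = 0.436), and it passed without MCK-PPARa replicate 3 (mean -0.49, adjusted p = 0.0114; adjusted p = 0.952 with an estimated correlation). The miR-23-27-24 clusters (mean 0.22), the miR-17-92 and paralogous clusters (-0.20), the miR-15/16 family (0.21), the miR-29 family (-0.06) and the muscle regeneration list (0.13) had no called member. Adjusted over the list alone, miR-20b, miR-181c and miR-221 passed in the miR-17-92 list, the miR-181 family and the list of miR-221 and miR-222. Adjustment over a list alone does not correct for the number of lists. miR-221 was at the floor in 2 of 3 NTGa animals, and its mean level in MCK-PPARa (-3.66) was close to that in NTGb (-4.06).

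Among markers of other cell types in MCK-PPARa, none was called. The leukocyte list had a mean log2 change of 0.28 (5 of 6 positive), the smooth muscle and fibroblast list 0.21 (5 of 5 positive) and the neural list 0.41, although its median was -0.14. Endothelial miR-126-3p was at 0.27 and miR-126-5p at -0.85, and erythroid miR-451 at 0.58 (adjusted p = 0.42). Of 8 epithelial microRNAs 2 could be tested, miR-182 at 1.60 (SE 0.89) and miR-200c at -0.40 (SE 1.15). None of the 6 microRNAs of other organs could be tested, and liver miR-122 was detected in 1 animal, of MCK-PPARb. MCK-PPARa replicate 1 had the lowest median correlation with the other animals, 0.943, where the rest had 0.964 to 0.981. Without it 4 microRNAs were called, miR-499 (log2 -3.61), miR-190b (-2.57), miR-215 (1.98) and miR-194 (1.40).

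In MCK-PPARb soleus, limma called no microRNA changed against NTGb. The count at an unadjusted p under 0.05 was 23, of which 14 were higher and 9 lower. The groups did not overlap for 41 microRNAs (15.3%, chance 10% on average), a share not compared with that of other splits. The lowest p belonged to miR-135a, 8.62-fold higher (log2 3.11, SE 0.67, adjusted p = 0.211). It was called with animal weights (log2 3.67, adjusted p = 0.00686) and without NTGb replicate 2 (3.93, adjusted p = 0.0102), and its adjusted p ran from 0.00686 to 0.705 over the alternatives. The log2 value of miR-135a was 2.45 without MCK-PPARb replicate 3, 1.12 at a limit of Ct 32, 4.76 with no detection limit and 1.24 against all 6 controls, and its sign turned against NTGa (-0.62). The mean level was -5.58 ± 1.43 (n = 3) in NTGb and -1.85 ± 0.171 in NTGa. NTGb replicate 2 lay farthest from its own group, with 296 microRNAs detected against 261 and 248, and a median absolute log2 difference of 0.48 and 0.55 from the other NTGb animals, where the remaining pairs within a group had 0.28 to 0.36. The 2 microRNAs of the slow myosin genes gave miR-208b at log2 1.32 (SE 0.62, limma adjusted p = 0.532) and miR-499 at -0.08 (SE 0.30), and miR-208b was at 0.86 without NTGb replicate 2. miR-208, of the cardiac myosin gene Myh6, had a Ct of 32.1 to 32.2 in 2 MCK-PPARb animals and none in MCK-PPARb replicate 3, so it was not tested. Leaving out MCK-PPARb replicate 3 let miR-208 enter the test and gave 1 call, which follows from removing the animal without a Ct.

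The muscle-enriched list did not shift in MCK-PPARb (camera adjusted p = 0.796), with miR-1 at 0.25, miR-133a at -0.21, miR-133b at 0.14, miR-206 at 0.09 and miR-486 at -0.28. The values of lowest p on the higher side included miR-28 (0.94), miR-185 (1.28), miR-24-2* (0.77), miR-547 (1.00), miR-98 (1.34), miR-340-3p (0.73), miR-192 (0.60) and miR-194 (0.62). On the lower side were miR-184 (-1.60), rno-miR-204* (-1.19), rno-miR-339-3p (-0.91), miR-485* (-2.10), miR-29b (-0.68), miR-148b (-1.14) and miR-335-5p (-0.73). Leaving out 1 animal moved miR-485* to -1.22 (NTGb replicate 2), miR-148b to -0.72 (MCK-PPARb replicate 2) and miR-185 to 0.83 (MCK-PPARb replicate 1). miR-380-5p was at the floor in all 3 MCK-PPARb animals, at least 2.65-fold lower. None of these passed, and their adjusted p lay between 0.49 and 0.532.

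In MCK-PPARb, 2 lists passed camera at the preset correlation. The miR-23-27-24 clusters rose as a list, with 4 of 4 tested members positive and a mean log2 change of 0.47 (adjusted p = 0.0199; adjusted p = 0.521 with an estimated correlation). miR-23b was at 0.63, miR-24 at 0.43, miR-27a at 0.41 and miR-27b at 0.40. The Dlk1-Dio3 cluster fell as a list, with 16 of 19 members negative and a mean of -0.42 (adjusted p = 0.0219; adjusted p = 0.521 with an estimated correlation). miR-411 was at -0.80, miR-134 at -1.45 and miR-539 at 0.82 among its members of lowest p; without NTGb replicate 2, miR-411 was at -0.49 and miR-134 at -0.81. No single member of either list passed, over all assays or adjusted over the list alone. Both list calls were lost with fry and without NTGb replicate 2 (0 lists; the miR-23-27-24 clusters at 0.32, adjusted p = 0.153, and the Dlk1-Dio3 cluster at -0.10, adjusted p = 0.642). Both were also lost without MCK-PPARb replicate 1 (0 lists; adjusted p = 0.0535 and 0.0732), and that of the Dlk1-Dio3 cluster without MCK-PPARb replicate 2 (1 list; adjusted p = 0.0699). Without NTGb replicate 1 the mean of the Dlk1-Dio3 cluster was -0.64. With U6 snRNA as reference, which moved the median of all microRNAs from 0.02 to 0.33, the means were 0.78 for the miR-23-27-24 clusters and -0.13 for the Dlk1-Dio3 cluster, with 11 of 19 members negative. Both list calls were kept with that reference (camera adjusted p = 0.00203 for each). The call of the miR-23-27-24 clusters was lost with the median reference and against NTGa (adjusted p up to 0.112). That of the Dlk1-Dio3 cluster was lost at a limit of Ct 32, with undetected values missing and with microRNAs detected in all 12 animals (adjusted p up to 0.215).

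The other 11 lists tested in MCK-PPARb had adjusted p from 0.117 to 0.842. The let-7 family had 8 of 9 members positive (mean 0.35, adjusted p = 0.117) and the leukocyte list 5 of 6 negative (mean -0.25, adjusted p = 0.177). The miR-29 family had 3 of 3 negative (mean -0.31). Means were 0.14 for the metabolism-associated list, -0.25 for muscle regeneration, -0.08 for smooth muscle and fibroblast, -0.03 for neural, 0.15 for the miR-30 family, -0.13 for the miR-17-92 clusters and 0.01 for the miR-15/16 family, whose test pointed down and whose median was 0.30. The median of the smooth muscle and fibroblast list was 0.08. The lists too short for the test gave endothelial -0.23, erythroid miR-451 at 0.53, epithelial 0.99, the miR-181 family 0.05 and the pair of miR-221 and miR-222 0.49 as means.

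The difference between the effects of the transgenes was tested directly. miR-499 differed by log2 -3.58 (SE 0.43, limma adjusted p = 0.00141), miR-215 by 2.22 with undetected values at the floor (adjusted p = 0.00612) and miR-190b by -2.22 (SE 0.43, adjusted p = 0.0313). miR-215 was at the floor in all 3 NTGa and all 3 MCK-PPARb animals, so the size of its difference was not measured. The SD of 0 in these groups may also make its p too small. In MCK-PPARb, miR-190b stood at 1.07 ± 0.302 against 1.10 ± 0.333 in NTGb. These were the only 3 calls of 268, with 28 at an unadjusted p under 0.05. The values of miR-208b (-2.63 or lower, since it was at the floor in all 3 MCK-PPARa animals; limma adjusted p = 0.236) and miR-486 (0.96) did not pass over all assays. Adjusted over the list alone, 2 of 2 myosin-gene and 3 of 7 muscle-enriched microRNAs passed, namely miR-499, miR-208b and miR-486. miR-192 and miR-194, called in MCK-PPARa alone, were not called in the difference.

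**Figure D3:**
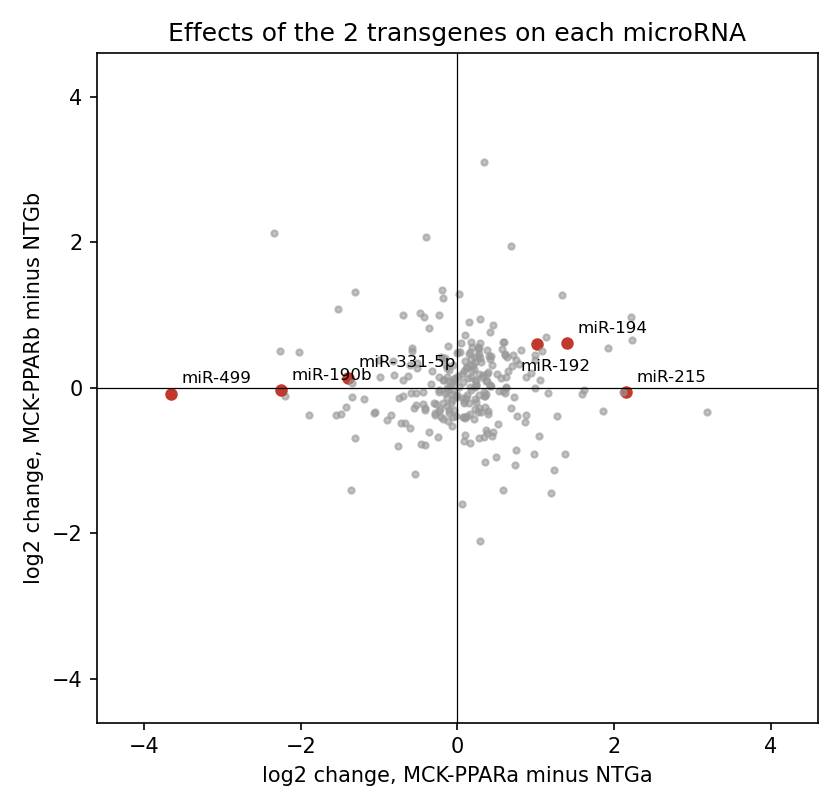
Log2 change of each of the 268 tested microRNAs in MCK-PPARa (horizontal axis, minus NTGa) and in MCK-PPARb (vertical axis, minus NTGb). Red points are the 6 microRNAs called in MCK-PPARa; miR-499 lies at -3.66 and -0.08, and the points as a whole show no slope (r = -0.00829).

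Further values of low p in the difference, none passing, were miR-509-3p (-2.76), rno-miR-339-3p (1.89), miR-148b (2.37), miR-547 (-1.70), miR-202-3p (-2.60) and miR-425 (3.52). The transgenic groups stood close together for rno-miR-339-3p (MCK-PPARa -3.909, MCK-PPARb -3.902), miR-509-3p (-6.03, -5.96) and miR-425 (mean Ct 31.1 in both). Their differences thus lay mostly between NTGa and NTGb, where all were called. The transgenic groups stood farther apart for miR-148b, miR-547 and miR-202-3p. miR-509-3p was detected in 1 of 3 NTGb and 1 of 3 MCK-PPARb animals, so the size of its difference was not measured. For miR-331-5p, at the floor in all 3 MCK-PPARa and all 3 NTGb animals, the size of the difference was not measured. No list differed between the effects (camera adjusted p from 0.253 to 0.908); the leukocyte list came lowest, with 6 of 6 members positive and a mean of 0.53. Across the 268 microRNAs, which are not independent replicates, the effects had a Pearson r of -0.00829 and a Spearman rho of 0.0808. Of 100 relabellings within the lines, 94 gave as large an r (permutation p = 0.94), and 57.5% of microRNAs had the same sign. The call of miR-190b was lost without any NTGa animal, MCK-PPARa replicate 2 or 3, NTGb replicate 3 or MCK-PPARb replicate 1 or 2, taken singly, with an adjusted p up to 0.117, and under 6 of 15 alternatives (up to 0.28). That of miR-215 was lost under 3 of 12 alternatives (up to 0.425), and that of miR-499 under 0 of 15. Without NTGb replicate 2 there were 6 calls, and without NTGa replicate 3 there were 2. With U6 snRNA as reference 1 was higher and 6 lower, with the endogenous controls 1 and 1, and with the median reference 0 and 1.

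The 2 groups of controls were compared as a background for the lines. Between NTGa and NTGb, 5 microRNAs were called and 42 had an unadjusted p under 0.05. miR-135a (log2 3.73, adjusted p = 0.0339), miR-509-3p (2.69, adjusted p = 0.0339) and miR-331-5p (at least 2.63-fold, adjusted p = 0.0426) were higher in NTGa. miR-425 (-3.65, adjusted p = 0.0426) and rno-miR-339-3p (-1.89, adjusted p = 0.0339) were lower in it. miR-499 was at -0.69 (limma adjusted p = 0.303) and miR-208b at -1.49 (limma adjusted p = 0.285), lower in NTGa without passing over all assays; adjusted over the list alone, 2 of 2 myosin-gene and 0 of 7 muscle-enriched microRNAs passed. So did 2 of 11 metabolism-associated microRNAs, miR-33* (-2.10) and miR-210 (-1.77), and 2 of 2 in the list of miR-221 (-1.82) and miR-222 (-0.81). No list passed (adjusted p from 0.0939 to 0.995). The miR-30 family came lowest, with 5 of 5 members positive. Of the 5 calls, 1 was shared with those of MCK-PPARa, miR-331-5p; NTGa enters both comparisons, so opposite signs arise by construction. The count fell to 0 without NTGa replicate 2, NTGa replicate 3, NTGb replicate 1 or NTGb replicate 3, to 2 without NTGa replicate 1 and to 3 without NTGb replicate 2. By reference it was 26 higher and 3 lower with U6, 2 and 5 with the median, 3 and 1 after quantile normalization and 5 and 1 with no scaling.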

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

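The tests of scaling, of single animals, of another muscle, of carried-over RNA, of the miR-215 assay and of the controls were chosen only after the results were seen, while the counts of splits were planned before.

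miR-499, miR-215 and miR-190b were flagged because they were called in the test of the difference of effects. Of these, the call of miR-190b was lost without several single animals, and the size of the difference of miR-215 was not measured. The difference of effects was -3.58 for miR-499, -2.22 for miR-190b and, with undetected values at the floor, 2.22 for miR-215 on the log2 scale. In 9 of 100 relabellings within the lines as many microRNAs were called, with 3 in the real one and up to 7 in another, so chance cannot be excluded for that count. For MCK-PPARa against NTGa the real split gave 6 calls and the highest other 0 (1 of 10 splits with as many). For MCK-PPARb against NTGb the real split gave 0 and the highest other 3 (10 of 10 with as many). In both lines the splits are too few for a share under 0.05.

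The fall of miR-499 in MCK-PPARa did not depend on the scaling reference or on a single MCK-PPARa animal in the tests run. Under 5 other references for scaling, the change nearest to 0 was -3.31, and without each MCK-PPARa animal in turn it was -3.48. A muscle with fewer slow fibres, sampled in place of the soleus, is a candidate explanation. miR-206, which the soleus holds at a high level, had a lower 95% bound of -0.17, and 1 marker does not settle the question.

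The rise of miR-192, miR-194 and miR-215 in MCK-PPARa was set against carried-over RNA of liver, pancreas or epithelium. The number of detected marker microRNAs of those tissues, out of 14, was not higher in MCK-PPARa. MCK-PPARa animals detected 1.67 ± 0.577 (n = 3) of them against 3 ± 1 in NTGa, a difference of -1.33. In MCK-PPARa, 11 of 14 were detected in no animal, miR-122 had no Ct, and the lowest Ct of any was 31.3, where miR-192 had a mean of 27.7. A count cannot register a rise in a marker detected in both groups. Epithelial miR-182, detected in all 3 animals of NTGa and of MCK-PPARa, was at log2 1.60 in MCK-PPARa. The other tested marker, miR-200c, was at -0.40, and neither was called, so carry-over from epithelium stays open. miR-215 rose by at least 1.14 more than miR-192, since it was at the floor in all 3 NTGa animals, so a miR-215 assay that reads miR-192 alone does not account for it. Under 5 other references the lowest mean change of the 3 was 1.44.

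The lower level of miR-331-5p in MCK-PPARa could reflect NTGa standing apart from the other groups. With no detection limit, MCK-PPARa lay 2.34 above NTGb, MCK-PPARb 2.12 and NTGa 4.67. Only 2 NTGb animals had a Ct, and the empty one was set to the floor, so these distances from NTGb were not measured. The means were -4.28 ± 0.716 (n = 3) in NTGa, -6.60 ± 0.433 in MCK-PPARa and -6.82 ± 1.72 in MCK-PPARb. The values of MCK-PPARa and NTGa were near the detection limit, so the test could not decide.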

How the results depend on the processing

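The mean over called wells, and the comparisons with the other line's controls and with all 6 controls, were chosen after seeing the data; the other alternatives were set before.

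Counts of called microRNAs moved most between the controls. Against 5 calls for NTGa and NTGb, there were 29 with U6, 14 with animal weights, 1 with no detection limit, 1 with no filter, and 0 with a limit of Ct 32, with undetected values missing or with microRNAs detected in all 12 animals. Leaving out 1 animal gave 0 to 3. The difference of effects had 3 calls, 7 with U6, 1 with the median reference and 2 to 6 without 1 animal. MCK-PPARb against NTGb had 0 calls by limma, 23 at an unadjusted p under 0.05, 1 with animal weights and 0 to 1 without 1 animal. MCK-PPARa against NTGa had 4 to 8 calls without 1 animal.

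List calls in MCK-PPARa were 0, but 1 with no detection limit, 1 with no filter and 0 to 1 without 1 animal. With no limit or no filter that was the myosin-gene list, of which miR-208 had no Ct in either group, so the list call rests on miR-499 and miR-208b; with an estimated correlation it was lost (adjusted p = 0.144 with no limit and adjusted p = 0.143 with no filter). In MCK-PPARb they were 2, but 1 with the median reference, with a limit of Ct 32, with undetected values missing, with microRNAs detected in all 12 animals or with the other line's controls. They were 6 with no filter, 0 with an estimated correlation, 0 with fry and 0 to 3 without 1 animal. The real split gave 2 lists and the highest other 5, and for MCK-PPARa 0 and 2; the splits are too few for a share under 0.05. The mean of the Dlk1-Dio3 cluster was -0.65 over 25 members with no detection limit and -0.25 over 44 with no filter.

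The median change of all microRNAs was 0.12 in MCK-PPARa, but 0.033 with U6, 0.21 with the median reference, 0.20 after quantile normalization and -0.003 with no scaling. In MCK-PPARb it was 0.02, but -0.05 with the median reference, 0.33 with U6 and 0.15 after quantile normalization or with no scaling. For the difference it was 0.06, but -0.35 with U6, 0.26 with the median reference, -0.06 with the endogenous controls and -0.11 with no scaling. Between the controls it was -0.03, but 0.49 with U6, 0.21 with the endogenous controls, -0.22 with the median reference and 0.29 with no scaling.

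Endogenous controls taken singly differed in Ct between MCK-PPARa and NTGa by 0.311 (snoRNA202) and 0.347 (Y1) and by -0.21 (U87) on card A, and by 0.293 (snoRNA202), -0.565 (Y1) and -0.26 (U87) on card B; without 1 animal their mean ran from -0.114 to 0.181. Between MCK-PPARb and NTGb, snoRNA135 on card A differed by 0.498 and Y1 by -0.724 on card A and -1.08 on card B; without 1 animal the mean ran from -0.36 to 0.119.

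In MCK-PPARa some values took the other sign. miR-1 was at 0.00013 with the median reference, 0.23 after quantile normalization, 0.17 against NTGb and 0.028 against all 6 controls. miR-133a was at 0.033 with the median reference. miR-133b was at -0.055 with U6, -0.052 with no scaling and -0.0024 against NTGb. Against NTGb, miR-206 was at -0.31, miR-425 at -0.46 (3.19 against NTGa), miR-509-3p at 0.43 (-2.26) and miR-741 at 0.33 (-2.02). Without 1 animal, miR-1 ran from -0.19 to -0.052, miR-133a from -0.15 to -0.039, miR-133b from 0.076 to 0.21 and miR-206 from 0.22 to 0.48.

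In MCK-PPARb miR-499 was at 0.019 with the endogenous controls, 0.23 with U6, 0.082 after quantile normalization, 0.61 against NTGa, 0.26 against all 6 controls and -0.39 to 0.16 without 1 animal. miR-133a was at 0.10 with U6 and -0.58 to 0.014 without 1 animal. miR-133b was at -0.048 with the median reference, -0.073 with animal weights and -0.15 to 0.28 without 1 animal. miR-206 was at -0.042 with no detection limit, -0.0498 with animal weights and -0.10 to 0.19 without 1 animal. miR-486 was at 0.031 with U6 and -0.51 to -0.10 without 1 animal, and miR-1 at 0.031 to 0.38 without 1 animal. Against NTGa, miR-1 was at -0.032, miR-135a at -0.62, miR-192 at -0.078, miR-184 at 0.76, rno-miR-339-3p at 0.99 (0.041 against all 6 controls), miR-148b at 0.34, miR-335-5p at 0.0092 and miR-134 at 1.05.

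The labels do not say that replicate numbers pair the animals, and a correlation over 0.1 in every pair was not found in either line. Same-numbered animals correlated at -0.18, 0.14 and -0.13 in the PPARa line and at 0.35, 0.03 and 0.27 in the PPARb line, and 1 of 3 and 3 of 3 matched their own number best, a hint from the data in the PPARb line. With the replicate number as a block, the calls were 5 in MCK-PPARa, 0 in MCK-PPARb, 1 in the difference and 6 between the controls, with 0 and 2 lists.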

Other observations

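The test of neighbouring microRNAs and the counts of splits were planned before their results were seen, while the remarks on miR-208 were chosen only after.

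Of the microRNAs of the myosin genes, miR-499 was detected in all 12 animals, and miR-208 in 3 animals of the PPARb line. miR-208, which lies in Myh6, had no Ct in any NTGa or MCK-PPARa animal. In NTGb 3 animals had a Ct of 34.5 to 37.3, 1 of them under the limit of 35, and in MCK-PPARb 2 animals had 32.1 to 32.2. miR-208b, which lies in the slow myosin gene Myh7, had a Ct of 31.8 to 34.4 in NTGa and, in 1 MCK-PPARa animal, of 39.2. Its mean Ct was 31.9 ± 0.659 (n = 3) in NTGb and 30.5 ± 0.694 in MCK-PPARb, and these values did not pass.

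MicroRNAs within 10000 bases of each other in the RefSeq table of GRCm38.p6 may share 1 transcript, and a hypothesis is that they changed alike. Over 158 pairs from 105 microRNAs, the changes of neighbours had a correlation of 0.27 in MCK-PPARa (1-sided permutation p = 5e-04, 95% of shuffles under 0.11). In MCK-PPARb it was 0.19 (1-sided permutation p = 0.0079, 95% of shuffles under 0.11). The same sign held for 63.3% and 60.1% of pairs. Shared animals and shared assay sequence could also make neighbours alike, which this test does not separate. Some pairs were both strands of 1 hairpin, such as miR-24 and miR-24-2*, which could do the same.

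The 2 control groups differed by 5 called microRNAs in the real split and by up to 2 in the others (1 of 10 splits with as many), and the splits are too few for a share under 0.05. The labels give no run or date, so a difference between lines or runs was not separated here. For lists, 10 of 10 splits in MCK-PPARa and 2 of 10 in MCK-PPARb had as many calls as the real one, with 0 and 2 in the real ones and up to 2 and 5 in others.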
